A study of Mus musculus with 15 samples.

How the data were processed

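RNA-seq and H3K4me1/2 ChIP-seq of B220-enriched mouse lymphoma cells were analysed from the files the authors deposited. Each RNA library came as 1 table of whole-number counts per gene, deposited by the authors without normalization. HTSeq 0.6.0, CASAVA 1.8.2 and the mouse build mm9 are named in the submitters' processing notes, and the aligner, the gene annotation and the use of strand are not given in the sources used here. Per the labels, RNA was purified with a Qiagen RNeasy Plus kit and libraries were made with an Illumina TruSeq RNA kit, which as far as known does not mark the strand, so reads of overlapping and antisense genes cannot be told apart. Each table held 37583 gene rows and 5 summary rows. The summary rows for alignments that were not unique (36.48% to 73.68% of all alignments), outside genes (2.69% to 12.93%) or ambiguous (0.83% to 1.35%) were kept out of library sizes and tests. Because reads that map to several places were not counted on genes, genes with near-identical copies are undercounted, among them Gapdh (5.45 to 14.1 CPM) and Rps27a (16 to 40.2 CPM). Gene counts per library ran from 5925745 to 29284830, and the share of alignments counted on genes from 22.8% to 49.36%.

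Each ChIP library came as 1 peak list of 11 columns without a header, called per library, in mm9 coordinates per the labels. The deposited lists give a peak's start and end, a score in columns 4 and 5, and in column 7 a whole-number signal per peak, which the authors left unlabelled. The peak caller, its threshold, any input control and whether starts count from 0 or 1 are not given in the sources used here, and coordinates are printed as listed. Scores were used only to rank peaks within a list, since values of different lists share no known scale. Sequencing depth of the ChIP libraries is unknown.

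Samples were grouped by the vector stated in the labels, and replicate numbers follow the order of the samples. Nothing in the labels says that the libraries came from separate animals, and if some share an animal the p-values measure only the spread between these samples. The series' own design text gives 3 samples per group, while the RNA files hold 4 and 5. No pair of RNA libraries agreed within sampling noise, as the chi-square per gene was at least 25.2. Symbols for 32860 of the 37583 gene identifiers (87.4%) were taken from a table of identifiers and symbols and, where it had none, from a RefSeq gene table of assembly GRCm38.p6, used for names only. 6 rows whose symbol is not unique keep their identifier. Reference genomes and coordinates of other builds were not used.

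The RNA comparison used edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, robust quasi-likelihood F-test, two-sided) on 4 EV against 5 sh-Kmt2d libraries, with Benjamini-Hochberg adjusted p under 0.05 as the threshold, and 13349 genes passed the filter. CPM values are scaled by TMM unless said to be by total counts. Standard errors of log2 fold changes are approximate, from the fold change and its F statistic. Gene lists were tested with camera from limma 3.58.1 on voom values with a preset correlation of 0.01, two-sided, adjusted over 27 lists with at least 3 tested members, and again with an estimated correlation and with fry. Since camera takes no block, the lists were tested with the title number as a random block by cameraPR on the moderated t of the blocked fit, which without the block gives the adjusted p of camera. The choice of cameraPR was made after the data were seen. A list of sex-linked genes stayed out of that family. DESeq2 1.42.0 served as an alternative. Single measures per library were compared by exact permutation over all 126 splits into 4 and 5 (all two-sided) or over the 20 ordered splits of the 6 ChIP lists.

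The rule for named genes was fixed before the data were examined. It takes Kmt2d, up to 12 genes per direction with the largest fold change among those past the threshold with a mean of at least 5 CPM in a group and no overlap of the groups (immunoglobulin and T cell receptor segments, unnamed models and pseudogenes left out), up to 4 passing members of each list or else the 2 of smallest p with values only, and, where no gene passes, the 10 genes of smallest p. For regions it takes the 5 longest per direction. Of the list members that the rule takes, 1 is left out of the text. Genes named outside it, such as the long- and short-transcript genes (25 each, chosen by their known size after the libraries' gradient was seen), were chosen after their values were seen.

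Peaks of the 6 lists were joined where they overlapped by at least 1 base, and a region was in a list if a peak of that list was part of it. Overlap of lists was measured as the Jaccard index of covered bases (Python 3.11.15, pandas 2.3.3, numpy 2.4.6). Regions were not joined to genes, since an mm9 annotation was not used here.

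The tests were tried on simulated counts drawn from the real means, library sizes and dispersions of the 4 EV and 5 sh-Kmt2d libraries, among 13236 genes. edgeR recovered 62% of 100 genes changed by 4-fold and 98% of 100 changed by 16-fold with 10 false calls, and DESeq2 recovered 85% and 100% with 54 false calls among 12560 genes. With a smaller dispersion edgeR recovered 99% and 100% with 11 false calls among 13297 genes. camera called 100% of 2 planted lists and 0 others. Genes were drawn independently of each other, without the gradient that the real libraries share. These figures therefore do not show how the tests behave with correlated genes. In simulated peak lists all 200 and 100 planted regions were found. Each was planted in every list of its side and in no other list. The result therefore checks the counting only and not how lists with missed peaks behave.

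Alternatives were RLE size factors, total library size, DESeq2, voom with sample quality weights, robust estimation off, no filter on low counts, a mean CPM of at least 5, immunoglobulin genes left out (107 genes), the first title number as a random block, each library left out in turn, and for lists the estimated correlation and fry. For peaks they were an overlap of at least 50% of the shorter, the 27915 highest-scored peaks of each list, merging within 500 bases, the sex chromosomes left out, covered bases in place of peak numbers, and each list left out in turn. After the data were seen, 5 more were added: sh-Kmt2d replicates 4 and 5 both left out, the long-minus-short index as a term, the same term with an estimated correlation for lists, lists of equal covered length (21.02 Mb each), and sh-Kmt2d replicate 2 left out together with an EV list.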

Results

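The study set B cell lymphomas of mice that carried an empty vector (EV) beside lymphomas that carried a short hairpin RNA against Kmt2d (sh-Kmt2d), and asked what lower Kmt2d does to transcription and to histone H3 lysine 4 methylation in the tumour cells. Kmt2d encodes a histone methyltransferase that marks enhancers and is often mutated in human B cell lymphoma. The cells were taken straight from tumours and enriched with magnetic beads for CD45R (B220), a B cell surface marker. RNA sequencing covered 4 EV and 5 sh-Kmt2d libraries. Chromatin immunoprecipitation with an antibody against mono- and dimethylated H3 lysine 4 (H3K4me1/2) gave 1 peak list for each of 3 EV and 3 sh-Kmt2d libraries. Counts on genes per RNA library were 13024141, 13764747, 18653468 and 25539223 for EV replicates 1 to 4, and 29284830, 19465194, 14320718, 14739041 and 5925745 for sh-Kmt2d replicates 1 to 5. Between 16008 and 19775 genes had at least 1 count in a library. The lowest figure belonged to sh-Kmt2d replicate 5. EV replicate 2 held both Xist (85 CPM by total counts) and the Y-linked Ddx3y (161 CPM), and a mixed sample was not excluded for it.

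Kmt2d (ENSMUSG00000048154) was measured first, as a check of the labels. In the EV libraries it stood at 498, 252, 492 and 94.4 CPM (counts scaled to library size), and in the sh-Kmt2d libraries at 57.4, 46.8, 204, 18.85 and 9.775 CPM. The means were 334.1 ± 196.6 CPM (SD, n = 4) for EV and 67.3 ± 78.8 CPM (SD, n = 5) for sh-Kmt2d. The groups overlapped, because sh-Kmt2d replicate 3 lay above EV replicate 4. The log2 fold change of sh-Kmt2d over EV was -2.31 ± 0.84 (SE) and did not pass the test across all genes (edgeR quasi-likelihood, adjusted p = 0.167, and 0.0593 with DESeq2). The counts behind the extremes were 9828 in EV replicate 3 and 31 in sh-Kmt2d replicate 5.

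Other genes with very long transcripts had values like that of Kmt2d. Among 25 genes chosen for their long transcripts, log2 fold changes ran from -2.52 to -1.20 with a median of -1.66. Macf1, a cytoskeletal linker (-2.43 ± 0.73, SE), and Ahnak, a giant scaffold protein (-2.52 ± 0.75, SE), had more negative values than Kmt2d. Among 25 genes with short transcripts, mainly subunits of the respiratory chain, the median was 2.16 and the range 0.29 to 2.67, with Uqcrq at 2.67 ± 0.91 (SE) and Cox8a at 2.53 ± 0.88 (SE). sh-Kmt2d replicate 5 carried these values: Uqcrq stood at 888.5 CPM there and at 58.84 to 109.1 CPM in the other sh-Kmt2d libraries, and Cox8a at 1728 against 117 to 222.7 CPM. Without that library the median of the short genes was 0.79 and that of the long genes -1.38, and without sh-Kmt2d replicates 4 and 5 they were 0.60 and -1.08. None of these genes passed the adjusted threshold by edgeR. DESeq2 called Macf1 (adjusted p = 0.0283) and Ahnak (adjusted p = 0.0261) and no other of them. The difference between the median log2 CPM of the long and of the short genes, called the long-minus-short index below, was 2.59, 2.27, 2.76 and 0.82 in the EV libraries and -0.14, -0.48, 1.29, -2.33 and -5.74 in the sh-Kmt2d libraries. Its group means were 2.11 ± 0.88 (SD, n = 4) and -1.48 ± 2.71 (SD, n = 5), with p = 0.0317 in a two-sided exact permutation test and 0.0596 after Benjamini-Hochberg adjustment over 6 library measures. The genes of the index were chosen after this gradient between the libraries was seen, so that its p describes the libraries and is not an independent test. Kmt2d minus the median of the long genes averaged 0.53 ± 0.55 (SD, n = 4) in EV and -0.08 ± 0.41 (SD, n = 5) in sh-Kmt2d (exact permutation p = 0.0952, adjusted 0.0952).

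**Figure D1:**
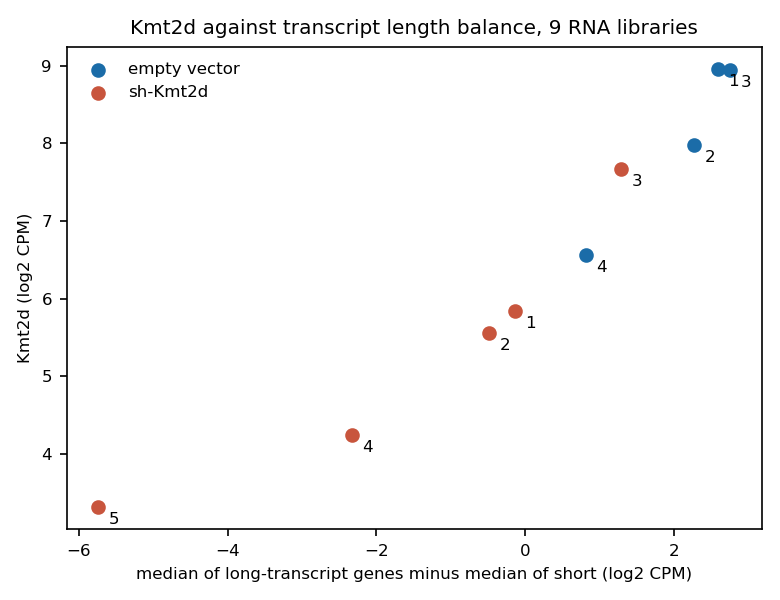
Kmt2d level (y axis, log2 CPM) against the long-minus-short index (x axis, log2) in the 9 RNA libraries, blue for empty vector and red for sh-Kmt2d, with replicate numbers beside the points. Kmt2d ran from 3.31 to 8.96 along the index, and sh-Kmt2d replicate 3 sits among the empty vector libraries.

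The libraries also differed in how reads were assigned. Alignments that the counting program could not place uniquely made up 41.3% ± 5.1 (SD, n = 4) of all alignments in EV and 56.0% ± 11.0 (SD, n = 5) in sh-Kmt2d, where replicate 5 reached 73.68% (exact permutation p = 0.0317, adjusted 0.0596). Alignments outside genes made up 10.4% ± 3.2 (SD, n = 4) and 4.70% ± 1.56 (SD, n = 5) in the same order (exact permutation p = 0.0159, adjusted 0.0596). The first principal component of log2 CPM held 77.4% of the variance between libraries and ran along the index, with a Pearson correlation of -0.985 and a Spearman correlation of -1. The index genes were chosen after this gradient was seen and are among the genes that make the component, so these correlations describe the libraries and test nothing. Without the 2 libraries farthest from the median index the Pearson correlation was -0.997. The first number in the library titles (78 and 87 for EV, 103 and 110 for sh-Kmt2d) differed within each group, and none spans both groups. The exact permutation tests of library measures above exchange libraries freely across these 4 title numbers, which allow no share under 0.333. The index averaged 2.59 and 1.95 for EV titles 78 (1 library) and 87 (3 libraries), and 0.22 and -4.03 for sh-Kmt2d titles 103 (3 libraries) and 110 (2 libraries). With the title number as a random block (correlation 0.439) limma called 0 genes.

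Single genes showed large differences between the groups, but none passed the adjusted threshold. The 10 genes with the smallest p were Ppbp, Hmgcll1, Dmrt3, Wnt10a, Cfap74, Lpl, Grk3, Impg1, Asph and Rgs1, and for each of them the 4 EV and 5 sh-Kmt2d libraries did not overlap. A choice by p favours such genes, and 10.84% of all tested genes had groups that did not overlap, so that this is not separate support. Ppbp, Hmgcll1, Dmrt3, Impg1 and Asph had means under 5 CPM in both groups and rest on few counts. Rgs1, a regulator of G protein signalling in activated B cells, had 136 ± 108 CPM (SD, n = 4) in EV and 14.99 ± 5.16 CPM (SD, n = 5) in sh-Kmt2d. Wnt10a, which encodes a secreted Wnt ligand, had 1.60 ± 0.68 CPM (SD, n = 4) in EV and 15.5 ± 8.6 CPM (SD, n = 5) in sh-Kmt2d. Ppbp, a platelet chemokine, had 1.47 ± 0.35 CPM (SD, n = 4) and 0.208 ± 0.076 CPM (SD, n = 5) in the same order.

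The edgeR quasi-likelihood test called 0 of 13349 genes higher and 0 lower in sh-Kmt2d. At an unadjusted p under 0.05 it counted 2306 genes higher and 1480 lower. DESeq2 called 234 higher and 444 lower, and limma with voom and sample quality weights called 3979 and 4045. Most of the short genes, Uqcrq and Cox8a among them, had no adjusted p by DESeq2 and so could not be among its calls. The quality weights were highest for sh-Kmt2d replicate 1 (7.63) and EV replicate 3 (4.017), on which those counts lean. The smallest adjusted p was that of Ppbp, with a log2 fold change of -2.91 ± 0.34 (SE) and adjusted p = 0.0943. The other 9 genes had adjusted p = 0.167. Their log2 fold changes were 4.02 ± 0.55 (SE) for Hmgcll1, an enzyme of leucine breakdown, 2.98 ± 0.42 for Dmrt3, a transcription factor, 3.23 ± 0.48 for Wnt10a and 2.89 ± 0.50 for Impg1, a matrix protein of the retina. They were -1.46 ± 0.22 for Cfap74, -2.92 ± 0.45 for Lpl, the lipoprotein lipase, -2.50 ± 0.42 for Grk3, a kinase that desensitises G protein-coupled receptors, -1.53 ± 0.27 for Asph and -3.18 ± 0.565 for Rgs1. DESeq2 gave each of these 10 an adjusted p between 2.25e-08 and 0.000644. With sh-Kmt2d replicates 4 and 5 left out, edgeR again called 0 genes in either direction, with 1599 higher and 2000 lower at an unadjusted p under 0.05. The unadjusted counts moved by over 1.5 times without single libraries. The higher genes numbered 605, 909 and 560 without EV replicates 1, 2 and 3. The lower genes numbered 777 and 786 without EV replicates 1 and 3, and 2296, 870 and 2445 without sh-Kmt2d replicates 3, 4 and 5. Without EV replicate 4, edgeR called 1 gene lower after adjustment. Groups that did not overlap were seen for 1447 genes, 10.84% of those tested. Free exchange of the libraries would give 1.59%, but it ignores the title numbers and the shared gradient between libraries, so that an excess is not shown.

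**Figure D2:**
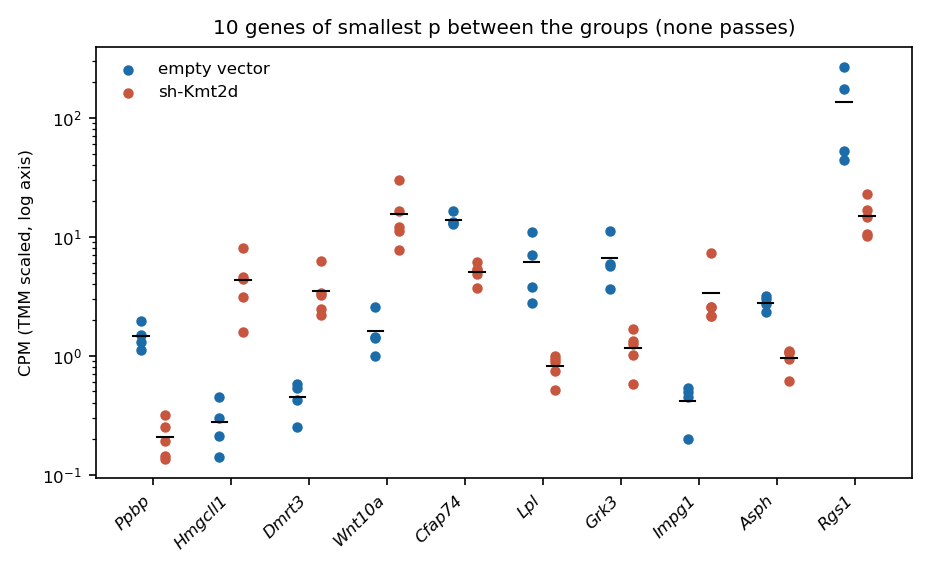
CPM (TMM scaled, log axis) of the 10 genes of smallest p in each RNA library, blue for empty vector and red for sh-Kmt2d, with a line at each group mean. The groups are apart for every gene shown, with Rgs1 at 136 and 14.99 CPM on average, though no gene passed the adjusted threshold. The genes were picked by p from these same libraries.

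The members of the gene lists, the camera test and the rule for named genes were fixed before the data were examined. The index as a term (also with an estimated correlation), the removal of sh-Kmt2d replicates 4 and 5 together and the use of cameraPR were chosen after the data were seen. Against all other genes, camera with its preset correlation placed 6 lists lower and 3 higher in sh-Kmt2d among 27 lists. Without EV replicate 2, or without sh-Kmt2d replicate 3, 1 list was higher. With the title number as a random block, tested by cameraPR, 5 lists were lower and 1 higher. When the index as a term was joined with an estimated correlation, camera called 0 of the 27 lists, and the smallest adjusted p was 0.614. The lower lists were the immediate-early and stress genes, the tumour suppressors named for KMT2D, the H3K4 methyltransferase complexes and demethylases, and the markers of macrophages, platelets and stroma. The higher lists were MHC class II presentation, glycolysis and the cell cycle. With an estimated correlation between genes none of the 9 calls held, and fry, which asks whether a list moves one way without comparing it with other genes, called the platelet list (adjusted p = 0.00102) and the stromal list (adjusted p = 0.0284) among the 27. Medians of lists below are of log2 fold changes from voom, and values of single genes are from edgeR with their SE.

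Immediate-early and stress genes, which cells switch on within minutes of a stimulus or of handling, were the list lowest in sh-Kmt2d. All 15 members had negative log2 fold changes, and their median was -1.85 (camera adjusted p = 3.18e-05; adjusted p = 0.797 with an estimated correlation). Of the 15, 12 passed by edgeR when adjusted over the list alone, and over all genes 0 did, while DESeq2 called 9. Dusp1, a phosphatase that ends MAP kinase signals, had 287 ± 190 CPM (SD, n = 4) in EV and 25.2 ± 15.6 CPM (SD, n = 5) in sh-Kmt2d, a log2 fold change of -3.51 ± 0.66. Egr1, a zinc finger transcription factor, had 618.5 ± 374 CPM (SD, n = 4) and 66.5 ± 51.7 CPM (SD, n = 5), a log2 fold change of -3.21 ± 0.74. The list's mean log2 CPM was 6.80, 8.17, 8.59 and 5.70 in the EV libraries and 5.57, 5.43, 6.2, 4.86 and 3.9 in the sh-Kmt2d libraries (exact permutation p = 0.0238). That test exchanges libraries freely across title numbers, whose means were 6.80 (78) and 7.49 (87) in EV and 5.73 (103) and 4.38 (110) in sh-Kmt2d, and 4 title numbers allow no share under 0.333. With the title number as a random block the median was -1.43 (cameraPR adjusted p = 0.000761), and neither Dusp1 nor Egr1 passed (limma adjusted p = 0.404). With the long-minus-short index as a term the median was -0.74 and the list stayed lower (camera adjusted p = 0.0293; adjusted p = 0.725 with an estimated correlation). Without EV replicate 3 it was -1.18 (camera adjusted p = 0.000126).

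The 7 tumour suppressors that are named in the literature as depending on KMT2D in lymphoma all had negative values, with a median of -1.13 (camera adjusted p = 0.0032; adjusted p = 0.797 with an estimated correlation). Adjusted over the list alone, 7 of the 7 passed by edgeR, and over all genes 0 did, while 7 had an unadjusted p under 0.05 and DESeq2 called 1. Socs3, a brake on cytokine signalling, had 31.9 ± 7.6 CPM (SD, n = 4) in EV and 18.7 ± 1.9 CPM (SD, n = 5) in sh-Kmt2d (-0.77 ± 0.22). Sgk1, a kinase induced by serum and glucocorticoids, had 23.3 ± 12.6 CPM (SD, n = 4) and 9.35 ± 1.76 CPM (SD, n = 5) (-1.30 ± 0.42). The list was drawn from published work on KMT2D in lymphoma and is not independent evidence of its direction. With the index as a term its median was -0.18 and the call was lost (camera adjusted p = 0.256), and without sh-Kmt2d replicates 4 and 5 the median was -0.77 (camera adjusted p = 0.00199).

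The H3K4 methyltransferase complexes and demethylases, with Kmt2d among their 21 members, had 18 negative values and a median of -1.08 (camera adjusted p = 0.0127; adjusted p = 0.851 with an estimated correlation). Adjusted over the list alone, 0 passed by edgeR, while 7 were lower and 2 higher at an unadjusted p under 0.05 and DESeq2 called 0. Setd1a and Setd1b, which encode the catalytic subunits of the SET1 complexes, had log2 fold changes of -1.10 ± 0.34 and -1.96 ± 0.665. With the index as a term the median of the list was 0.22, and without sh-Kmt2d replicates 4 and 5 it was -0.30 (camera adjusted p = 0.0533). Without sh-Kmt2d replicate 5 alone it was -0.50 (camera adjusted p = 0.0282).

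MHC class II presentation had 10 positive values among 11 members and a median of 0.92 (camera adjusted p = 0.018; adjusted p = 0.851 with an estimated correlation). H2-Ab1 and H2-Aa, the chains of the I-A molecule, had 3709 ± 502 and 5269 ± 1022 CPM (SD, n = 4) in EV, and 9944 ± 8374 and 15450 ± 14310 CPM (SD, n = 5) in sh-Kmt2d, with log2 fold changes of 1.42 ± 0.535 and 1.55 ± 0.59, and of 0.75 and 0.80 without sh-Kmt2d replicate 5. Without sh-Kmt2d replicate 5 the list median was 0.58 and the call was lost (camera adjusted p = 0.0635). It was lost too without sh-Kmt2d replicates 4 and 5 (median 0.38, camera adjusted p = 0.099) and with quality weights (median 0.63, camera adjusted p = 0.086), and with the index as a term the median turned to -0.22 and the list was lower (camera adjusted p = 0.0293; adjusted p = 0.725 with an estimated correlation). Glycolysis had 11 positive values among 15 and a median of 0.70 (camera adjusted p = 0.026; adjusted p = 0.797 with an estimated correlation), with Ldha at 1.22 ± 0.43 and Eno1 at 1.12 ± 0.41. The cell cycle list had 18 positive values among 24 and a median of 0.46 (camera adjusted p = 0.0288; adjusted p = 0.851 with an estimated correlation), with Cdc20, an activator of the anaphase-promoting complex, at 1.01 ± 0.37 and Cdk1 at 1.33 ± 0.57. Without sh-Kmt2d replicate 5 Ldha stood at 0.78, Eno1 at 0.64 and Cdk1 at 0.68. Adjusted over the list alone, 0 members of these 3 lists passed by edgeR, and DESeq2 called 0. At an unadjusted p under 0.05, 7 members of the MHC class II list, 6 of glycolysis and 3 of the cell cycle list were higher. Over all 13349 tested genes 2306 were higher at that threshold. That is a larger share than 3 of 24 in the cell cycle list, and a smaller one than in MHC class II and glycolysis. Glycolysis lost its call without EV replicate 2 (0.0519) or sh-Kmt2d replicate 3 (0.161), and the cell cycle list without EV replicate 2 (0.237), EV replicate 3 (0.0777), sh-Kmt2d replicate 1 (0.0678) or sh-Kmt2d replicate 3 (0.29), all camera adjusted p. With total library size the cell cycle median was 0.22 and its call was lost (camera adjusted p = 0.0705). Both lists lost their calls with the title number as a random block (cameraPR adjusted p = 0.0587 for glycolysis and 0.0865 for the cell cycle), and with the index as a term, where the medians were 0.31 for glycolysis (camera adjusted p = 0.0806) and 0.36 for the cell cycle (camera adjusted p = 0.0909). Eno1 and other glycolytic genes have near-identical copies in the genome, so that their counts are uncertain, and Gapdh was at 5.45 to 14.1 CPM by total counts.

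Markers of macrophages, platelets and stroma were lower in the sh-Kmt2d libraries. The macrophage and monocyte list had 15 negative values among 16 and a median of -0.84 (camera adjusted p = 0.012; adjusted p = 0.851 with an estimated correlation). In it 5 members were lower when adjusted over the list alone. Mrc1, the mannose receptor, had a log2 fold change of -2.31 ± 0.555, and of -1.33 without EV replicate 1, and Itgam of -1.36 ± 0.39. Lyz2, among the most abundant of these markers, had 114 ± 71 CPM (SD, n = 4) in EV and 73.0 ± 21.0 CPM (SD, n = 5) in sh-Kmt2d by total counts. The macrophage call was lost without EV replicate 1 (median -0.36, camera adjusted p = 0.0619) or sh-Kmt2d replicate 3 (median -0.62, camera adjusted p = 0.0963). The platelet list had a median of -1.57 over 3 tested members (camera adjusted p = 0.0032; adjusted p = 0.323 with an estimated correlation), with Ppbp as above and Itga2b at -1.51 ± 0.31. The stromal and endothelial list had a median of -0.97 over 3 tested members (camera adjusted p = 0.0441, and 0.705 with an estimated correlation), with Vwf at -2.73 ± 0.61 and Cdh5 at -0.90 ± 0.37. These genes were at low levels. Mean CPM in EV and sh-Kmt2d were 2.82 and 0.98 for Itga2b, 0.83 and 0.11 for Vwf, and 2.03 and 1.01 for Cdh5. The median of the stromal list moved when single libraries were left out. This median was -1.46 without EV replicate 1 and -1.56 without EV replicate 2. The stromal list lost its call without EV replicate 4 (camera adjusted p = 0.0747) or sh-Kmt2d replicate 3 (camera adjusted p = 0.114), and with the title number as a random block (cameraPR adjusted p = 0.0865). Total library size (camera adjusted p = 0.0705) and quality weights (median -0.61, camera adjusted p = 0.19) ended the stromal call as well. The stromal median was -0.19 with the index as a term and the call was lost (camera adjusted p = 0.222), while the macrophage list (median -1.28, camera adjusted p = 7.99e-06; adjusted p = 0.725 with an estimated correlation) and the platelet list (median -1.33, camera adjusted p = 0.00349, and 0.614 with an estimated correlation) stayed lower.

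Other contaminating cell types were not called by camera without the index as a term. Among T cell markers Cd3g stood at 2.52 ± 0.50 and Cd4 at -1.37 ± 0.36, and the list median was 0.39 (camera adjusted p = 0.465). Adjusted over the list alone, 1 member was higher and 1 lower. Neutrophil markers had a median of -1.65 over 5 tested members, with S100a9 at -1.99 ± 1.12 and Ngp at -2.28 ± 1.43 (camera adjusted p = 0.347). With the index as a term the neutrophil median was -4.65 and the list was lower (camera adjusted p = 0.000104; adjusted p = 0.614 with an estimated correlation of 0.807). Both genes were highest in EV replicate 4, and without it S100a9 stood at 0.22 and Ngp at 0.92. Erythroid markers had a median of -0.04, with Slc4a1 at -3.78 ± 1.43, against an upward sign of the test (camera adjusted p = 0.918). EV replicate 4 held 95.3 CPM of Slc4a1, and without it the value was -1.10. NK cell markers had a median of 0.36, with Klrb1c at 2.20 ± 0.67 and Nkg7 at 1.03 ± 0.605 (camera adjusted p = 0.465). The plasmacytoid dendritic cell list had a median of -0.13, with Siglech at -1.91 ± 0.68 and Ly6d, which B cells express too, at 1.81 ± 0.72 (camera adjusted p = 0.768). Without sh-Kmt2d replicate 5 Nkg7 stood at 0.49 and Ly6d at 0.93.

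B cell programmes did not stand apart from other genes by camera without the index as a term. The mature B cell identity list had a median of -0.12, against an upward sign of the test (camera adjusted p = 0.736), with the IgM receptor Fcmr at 1.20 ± 0.41 and the chemokine receptor Cxcr5 at 0.70 ± 0.28. Germinal centre genes had a median of -0.02, against an upward sign of the test (camera adjusted p = 0.918), with Rgs13 at 0.82 ± 0.33 and the repressor Bach2 at -1.345 ± 0.60. With the index as a term the germinal centre median was 0.37 and the list was higher (camera adjusted p = 0.0259; adjusted p = 0.725 with an estimated correlation of 0.674). Plasma cell genes had a median of 0.40 (camera adjusted p = 0.204), with Xbp1, the regulator of the secretory programme, at 0.88 ± 0.32 and Mzb1 at 2.06 ± 0.76. Marginal zone and B-1 genes had a median of -0.40 (camera adjusted p = 0.465), with Notch2 at -1.57 ± 0.625 and Ctla4 at 1.09 ± 0.49. B cell precursor genes had a median of -0.37 (camera adjusted p = 0.621), with Vpreb3 at 2.50 ± 0.93 and Dntt at -1.79 ± 0.70. Without sh-Kmt2d replicate 5 Mzb1 stood at 0.88 and Vpreb3 at 0.79.

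Signalling lists were not called either without the index as a term. With it, B cell receptor signalling (median 0.22, camera adjusted p = 0.0406) and the JAK-STAT list (median 0.34, camera adjusted p = 0.0313) were higher, and neither call held with an estimated correlation (adjusted p = 0.725 for both). B cell receptor signalling had a median of -0.34 (camera adjusted p = 0.56), although the receptor's own chains Cd79b and Cd79a stood at 1.87 ± 0.63 and 1.52 ± 0.62, and at 0.99 and 0.67 without sh-Kmt2d replicate 5. CD40 and NF-kB signalling had a median of -0.11 (camera adjusted p = 0.621), with Nfkbiz at -1.60 ± 0.375 and Tnfaip3, a brake on NF-kB, at -1.43 ± 0.495. JAK-STAT and cytokine receptors had a median of -0.44 (camera adjusted p = 0.311), with Socs3 as above and Socs2 at 1.48 ± 0.47. Toll-like receptor signalling had a median of -0.30 (camera adjusted p = 0.753), with Ly96 at 1.78 ± 0.76 and Ly86 at 1.22 ± 0.55, or 0.61 and 0.56 without sh-Kmt2d replicate 5. Interferon-stimulated genes had a median of -0.17 (camera adjusted p = 0.621), with Rsad2 at -1.74 ± 0.555 (-0.92 without EV replicate 4) and Ifih1 at -0.91 ± 0.31.

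Among growth and death programmes, the p53 target list had a median of 0.17 (camera adjusted p = 0.362) over members that went apart. Cdkn1a, which encodes the cell cycle inhibitor p21, had 7.51 ± 2.46 CPM (SD, n = 4) in EV and 24.1 ± 11.2 CPM (SD, n = 5) in sh-Kmt2d (1.66 ± 0.39), while Plk2 had 27.4 ± 19.8 CPM (SD, n = 4) and 3.09 ± 1.23 CPM (SD, n = 5) (-3.10 ± 0.57). Adjusted over the list alone, 2 p53 targets were higher and 1 lower, and over all genes 0 passed. The Bcl2 family had a median of 0.25 (camera adjusted p = 0.347), with Pmaip1, a death-promoting member, at -1.57 ± 0.50 and Bik at 2.77 ± 0.91. Myc and nucleolar genes had a median of -0.26, against an upward sign of the test (camera adjusted p = 0.94), with Nop16 at 0.85 ± 0.33 and Rrp9 at 0.66 ± 0.32, or 0.52 and 0.33 without sh-Kmt2d replicate 5.

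**Figure D3:**
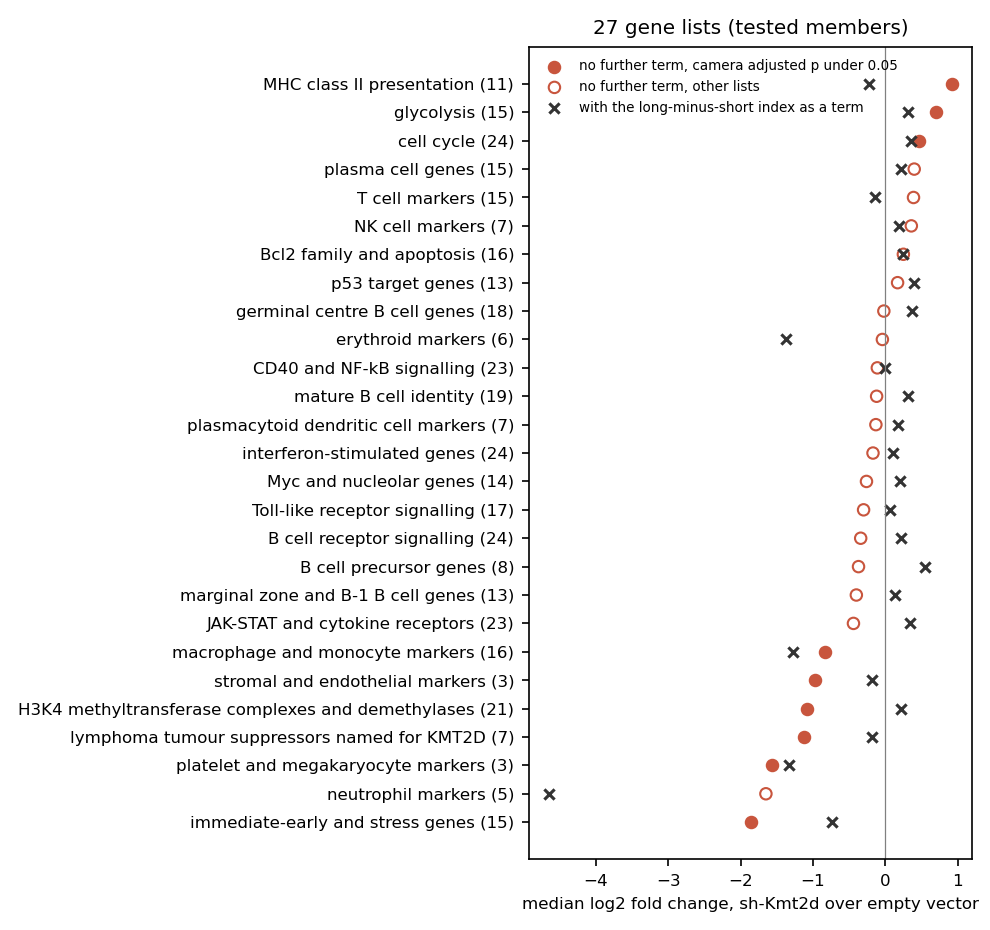
Median log2 fold change of sh-Kmt2d over empty vector (x axis) for each of 27 gene lists, with the number of tested members in brackets, filled circles where the camera adjusted p is under 0.05 and open circles elsewhere. Crosses give the median with the long-minus-short index as a term: the immediate-early list moved from -1.85 to -0.74, and MHC class II presentation from 0.92 to -0.22.

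Most H3K4me1/2 regions were shared by all 6 lists. The EV lists held 37479, 35863 and 37127 peaks and the sh-Kmt2d lists 36227, 37100 and 34894, which gives 36823 ± 850 (SD, n = 3) and 36074 ± 1111 (SD, n = 3), with p = 0.4 in a two-sided exact permutation test. Peaks of sh-Kmt2d replicates 1 and 3 were narrower than those of the other lists, with median widths of 630 and 614 bases against 733, 787 and 724 in EV and 747 in sh-Kmt2d replicate 2. The covered length was 33.7 ± 1.0 Mb (SD, n = 3) in EV and 29.5 ± 4.1 Mb (SD, n = 3) in sh-Kmt2d (exact permutation p = 0.3). With 3 lists against 3 the smallest p this test allows is 0.1, so that no difference could have passed and equality is not shown, and all 5 list measures had an adjusted p of 0.5. Of 40754 regions in the union of the lists, 25107 (61.6%) were in all 6, with a median length of 1167 bases.

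Regions that parted the groups were few and short. The 3 EV lists shared 423 regions that no sh-Kmt2d list held, with a median length of 473 bases. The 3 sh-Kmt2d lists shared 103 regions that no EV list held, with a median length of 447 bases. With the lists trimmed to equal covered length the counts turned round to 26 and 208. The longest of the EV regions lay on chromosome 9 from 103333585 to 103335483 (1898 bases) and from 37337453 to 37339041 (1588 bases), on chromosome 14 from 31641845 to 31643237, on chromosome 11 from 88396205 to 88397589 and on chromosome 2 from 93298685 to 93299995, all in mm9 coordinates as listed. The longest of the sh-Kmt2d regions lay on chromosome 15 from 38836295 to 38837607 (1312 bases) and, close by, from 38838494 to 38839551, on chromosome 4 from 149794630 to 149795864, on chromosome 18 from 24205110 to 24206119 and on chromosome 10 from 56759776 to 56760763. An mm9 gene annotation was not used here, so that regions were not placed on genes and the RNA of neighbouring genes was not compared. Triples of lists that mixed the groups held between 7 and 423 regions alone, the highest figure being that of EV replicates 1 and 2 with sh-Kmt2d replicate 2. Fewer lists have to match when a list is left out, and the 423 regions became 662, 947 and 896 without EV replicates 1, 2 and 3, and 1393 without sh-Kmt2d replicate 2. The 103 regions became 173 and 222 without EV replicates 2 and 3, and 238, 156 and 266 without sh-Kmt2d replicates 1, 2 and 3.

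**Figure D4:**
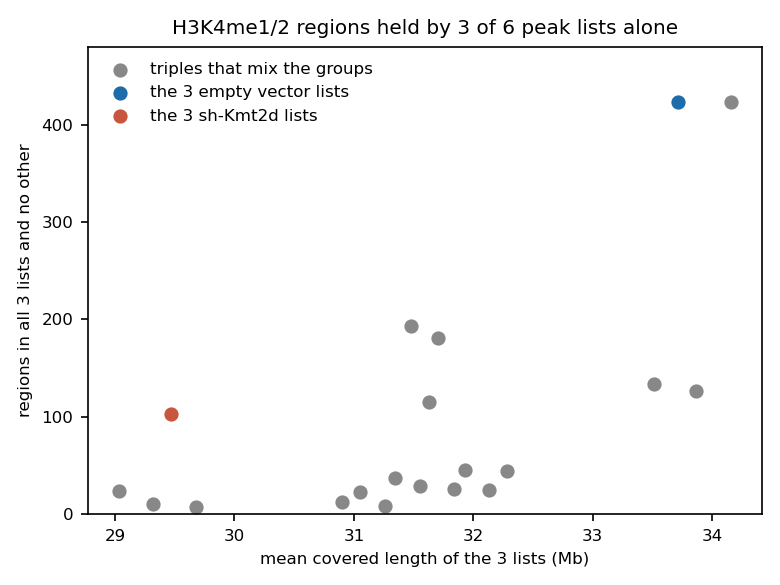
Number of H3K4me1/2 regions held by all of 3 lists and by no other (y axis) against the mean covered length of those 3 lists (x axis, Mb), for all 20 triples of the 6 lists. The empty vector triple in blue and a mixed triple in grey both reach 423 regions, and the sh-Kmt2d triple in red holds 103. Lists trimmed to equal covered length, not drawn here, gave 26 and 208.

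The overlap of peak lists did not part the groups beyond what other splits gave. The Jaccard index of covered bases averaged 0.769 ± 0.032 (SD, 6 pairs) within groups and 0.739 ± 0.048 (SD, 9 pairs) between them, a difference of 0.03 that 2 of the 10 splits of the 6 lists reached (exact p = 0.2, one-sided, where 0.1 is the smallest possible). The list of sh-Kmt2d replicate 2 overlapped EV replicates 1 and 2 at 0.804 and 0.801, and the other sh-Kmt2d lists at 0.744 and 0.73. Without it, the difference between within-group and between-group overlap was 0.074. The EV lists shared the first title number 87 and overlapped each other at 0.79 on average. The sh-Kmt2d lists, with title numbers 103 and 110, did so at 0.748. The splits exchange lists freely across title numbers.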

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

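The tests on Kmt2d, the long- and short-transcript genes, the long-minus-short index as a term and the split by index order were chosen after the data were seen, and the effects of the index and of a macrophage term on the immediate-early list were predicted before they were computed. A library was singled out where its gap to the nearest library of its group was a large share of the group's range on the log2 CPM scale. Chance gives this in about 1 of 20 groups, or 7.1 of the 142 groups looked at, and 15 were found. Of these, 6 lay in sh-Kmt2d replicate 5 and 5 in EV replicate 4. In sh-Kmt2d replicate 5 the values of Impg1 (gap over range 0.849), Vpreb3 (0.803), Ldha (0.8) and Eno1 (0.843) were far above, and those of Sgk1 (0.782) and Cd4 (0.865) far below, the other sh-Kmt2d libraries. In EV replicate 4 Eno1 (0.91) and S100a9 (0.84) were far above, and Socs3 (0.835), Egr1 (0.835) and Siglech (0.847) far below, the other EV libraries. Cfap74 was highest in EV replicate 1 (0.864), Asph lowest in sh-Kmt2d replicate 4 (0.74) and Mrc1 lowest in sh-Kmt2d replicate 1 (0.734). Kmt2d minus the median of the long genes was highest in sh-Kmt2d replicate 3 (0.806), at 0.63. By index, sh-Kmt2d replicate 5 was the lowest of its group at -5.74 and EV replicate 4 the lowest of its own at 0.82.

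Kmt2d had a log2 fold change of -2.31 ± 0.84 (SE). Loss of long transcripts from the libraries is a candidate explanation: with the long-minus-short index as a term the value was -0.44 ± 0.47 (SE). Of the 25 long genes, 2 had more negative values than Kmt2d, Ahnak (-2.52) and Macf1 (-2.43). A knockdown by the hairpin stays open too, since index and group go together and neither the lead of Kmt2d over most long genes nor these 2 exceptions decides. An shRNA can also lower a protein more than its mRNA, which RNA counts do not show.

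The immediate-early list had a median log2 fold change of -1.85 with the members spread by an SD of 1.19. With the index as a term the median was -0.74 (SD of members 0.64, camera adjusted p = 0.0293). The prediction for loss of long transcripts as the cause was a median within 1 SD of 0 and a lost call. At the preset correlation neither was seen. The term moved the median most of the way towards 0, but index and group go together. That shift therefore does not measure a share due to transcript length. With an estimated correlation the call was lost, both with the term (0.615, camera adjusted p = 0.725) and without it (camera adjusted p = 0.797), so that this argument rests on the preset correlation. With the mean of the macrophage markers as a term the median was -2.31 (SD of members 1.62), so that it did not move towards 0. The macrophage mean was 5.4 log2 CPM in EV replicate 1 and 2.77 to 3.96 in the other libraries. The term thus rests mainly on 1 library and cannot decide on fewer macrophages in the purified cells as the cause. Lower Kmt2d may lower these genes, and so may a difference in handling between tumours of different title numbers. With the title number as a random block the median was -1.43 (cameraPR adjusted p = 0.000761), but 4 title numbers, none of them in both groups, leave the explanation open, and a fixed term for them cannot be fitted beside the group.

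For genes called by edgeR the comparison of splits says nothing of chance: the real split called 0, so all 100 of the 100 splits drawn from 126 had to be as large, and the highest other called 0 too. At an unadjusted p under 0.05 the real split counted 3786 genes and 4 of the 100 splits counted as many, the highest other being 4570. That highest split placed EV replicates 1 to 3 and sh-Kmt2d replicate 3 against the rest, which is the order of the index. For lists called by camera chance cannot be excluded, since 39 of 100 splits called as many as the real 9 and the highest other called 17. For DESeq2 the real split called 678 genes, and 3 of 100 splits drawn were as large, the real split included. These splits exchange libraries freely, which ignores the title numbers and the shared gradient between libraries, so that chance is not excluded. At first 30 of these were run, with 1 as large and the highest other at 331, and the remaining 70 were added after that result was seen. The highest other of the 100 called 2428 genes, 381 of them shared with the real split, and the next called 1210. The highest is the split by index order, which has 2 libraries on another side than the real split, and edgeR called 0 genes in it. The index was chosen after the gradient between libraries was seen. The 2428 calls therefore describe that gradient and are not separate support for it.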

How the results depend on the processing

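The index as a term, alone or with an estimated correlation, sh-Kmt2d replicates 4 and 5 left out, lists of equal covered length and paired removals of peak lists were chosen after seeing the data, as was cameraPR for the lists under the random block. All other alternatives were chosen before the data were examined. No paired analysis was possible because the replicate numbers only follow the order of the samples and pair nothing, so that no block could be built from them. Genes higher and lower in sh-Kmt2d numbered 0 and 0 by edgeR, 234 and 444 by DESeq2, and 3979 and 4045 by voom with quality weights. The weight was 0.051 for sh-Kmt2d replicate 5, 7.63 for sh-Kmt2d replicate 1, 4.017 for EV replicate 3 and 0.373 to 2.252 for the others. The counts with quality weights thus lean on sh-Kmt2d replicate 1 and EV replicate 3. Total library size gave 1 lower gene, and the index as a term 3 higher. Leaving out 1 library gave 0 higher genes and 0 to 1 lower. With the title number as a random block (correlation 0.439) the counts were 0 and 0, and at an unadjusted p under 0.05 they were 280 and 939. The median of all genes shifted by -0.167 (log2) with total library size and by 0.109 with the index, and by under 0.1 otherwise. Lists higher and lower numbered 3 and 6 by camera, 0 and 0 with an estimated correlation, with or without the index, 0 and 2 by fry, and 1 and 5 with the title number as a random block, where the cell cycle, glycolysis and the stromal list lost their calls. Leaving out 1 library gave 1 to 3 higher lists and 4 to 6 lower. Of 187 values of the 9 called lists under alternatives, 136 kept direction and call, 47 lost the call and 4 reversed, all with the index, at the preset and at the estimated correlation: the H3K4 complexes at 0.22 and MHC class II at -0.22. Kmt2d ran from -3.33 to -2.03 without 1 library, with an adjusted p between 0.000621 (quality weights) and 0.632 (index) over all alternatives. Of 1236 values of 63 named genes, 1137 kept direction and side of the threshold, 81 newly passed and 18 reversed. With the index the reversed values were -0.04 for Cd79b, -0.38 for Cd79a, -0.62 for Ly96, -0.39 for Ly86, -0.29 for Mzb1, 0.08 for Notch2, -0.45 for Vpreb3, 0.59 for Dntt, -0.11 for H2-Ab1, -0.22 for H2-Aa, -0.03 for Cdk1, -0.03 for Nop16, -0.16 for Rrp9, -0.40 for Nkg7 and -0.18 for Ly6d. Slc4a1 was at 0.28 with quality weights. Without 1 library S100a9 ran from -2.74 to 0.22 and Ngp from -3.03 to 0.92, with the reversal without EV replicate 4. The cause of these changes was not tested. H3K4me1/2 regions of the EV lists alone and of the sh-Kmt2d lists alone numbered 423 and 103, and 26 and 208 with equal covered length. Without 1 list they ran from 460 to 1393 and from 135 to 266. Without sh-Kmt2d replicate 2 and EV replicate 1, 2 or 3 they were 1782, 2179 and 2332 and, in the same order, 206, 249 and 304. These counts rise by construction, since fewer lists have to match. An overlap of 50% of the shorter peak (402 and 94), 27915 peaks per list (290 and 83), merging within 500 bases (365 and 84) and leaving out X and Y (418 and 99) stayed within 1.5 times. The Jaccard difference of 0.03 ran from 0.016 to 0.074 without 1 list and gave no value for the 50% overlap. RNA beside lost regions at 10 or 50 kb was not run, since an mm9 annotation was not used here. At 31 counts of Kmt2d in sh-Kmt2d replicate 5, depth limits its precision there.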

Other observations

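The tests of other splits of the peak lists and the choice of the genes and immunoglobulin segments named here were made after the data were seen. The leading light chain variable segment differed between some libraries and was shared by others. Among 59 Igkv genes, Igkv5-48 reached 2525 CPM in sh-Kmt2d replicate 3, 48.8% of the Igkv counts there, and at most 315.9 CPM elsewhere. Igkv1-99 reached 3722 CPM in sh-Kmt2d replicate 5 (32.9%) and at most 90.3 CPM elsewhere, and Igkv2-137 reached 1581 CPM in EV replicate 1 (31.6%) and at most 575.1 CPM elsewhere. Igkv5-39 was the leading segment in EV replicate 2 (14.1%), sh-Kmt2d replicate 2 (923 CPM, 23%) and sh-Kmt2d replicate 4 (11.9%), and came next in EV replicate 3 (12.2%) and sh-Kmt2d replicate 3 (12.1%).

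Cd3g, a subunit of the T cell receptor complex, averaged 8.05 CPM in EV and 36.7 CPM in sh-Kmt2d by total counts, while Cd3d was at 3.74 and 8.65 CPM, Trbc2 at 4.03 and 6.19 CPM, Trac at 4.06 and 5.64 CPM and Cd3e at 3.18 and 3.61 CPM. With the index as a term, edgeR with Benjamini-Hochberg adjustment called 3 genes higher, each with adjusted p = 0.0391: Hmgcll1 (4.78 ± 0.55, SE), Fbn2, a fibrillin (5.59 ± 0.66, SE), and Prss23, a serine protease (7.69 ± 0.88, SE). Their mean CPM in EV and sh-Kmt2d were 0.276 and 4.36 for Hmgcll1, 0.264 and 3.32 for Fbn2, and 0.0376 and 3.25 for Prss23.

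Sex-linked transcripts differed between libraries of both groups. EV replicate 4 and sh-Kmt2d replicate 3 held Xist, the RNA of the inactive X, at 221 and 453 CPM and Ddx3y, a Y-linked helicase, at 0.235 and 0.279 CPM. EV replicate 2 held both, Xist at 85 CPM and Ddx3y at 161 CPM, so that a mixed sample was not excluded for it, and EV replicate 3 held Xist at 5.84 CPM. The peak lists that share the titles of those Xist-positive, Ddx3y-low libraries, EV replicate 3 and sh-Kmt2d replicate 1, held 0 peaks on the Y chromosome, and the remaining lists held 10, 10, 7 and 6. Sex was therefore not split along the groups.

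H3K4me1/2 regions of the EV lists alone (423) outnumbered those of the sh-Kmt2d lists alone (103). Broader EV lists are a candidate explanation: lists trimmed to equal covered length gave 26 and 208 regions, a ratio of 0.12 against 4.11 untrimmed. That trimming left 14258 to 16015 peaks in EV lists and 15092 to 20560 in sh-Kmt2d lists, so that it turned the difference round and cannot decide, and at equal peak number the counts were 290 and 83. A loss of H3K4 methylation with lower Kmt2d stays open, as does a difference in the depth of the ChIP libraries, which is unknown. A difference between title numbers stays open too. All EV lists had the first title number 87, and sh-Kmt2d replicates 1, 2 and 3 had 103, 110 and 110. None spans both groups, so that title number and group cannot be told apart. The real split gave 526 regions on both sides together and the highest other split 447, so that 1 of the 10 splits was as large, and 10 splits are too few for a share under 0.05.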
